A study of Homo sapiens with 21 samples.

How the data were processed

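RNA of sorted tumor-associated macrophages was measured on Affymetrix 3' expression arrays, 1 per sample: 12 arrays of untreated tumors, 5 of imatinib-sensitive and 4 of imatinib-resistant tumors. Per the labels' protocols, freshly obtained tumors were digested with collagenase. Cells carrying KIT, CD3 or CD56 were depleted with microbeads and CD14-positive cells were then selected. RNA was taken with RNeasy Plus Mini columns, and 200 ng of each was turned into biotin-labelled cRNA. The deposited intensity values are MAS5 signals from the Affymetrix Expression Console, per the submitters' processing notes. The software version and its further settings are not given in the sources used here. The values were linear, and the trimmed mean (2% off each end) of every array was about 500, which sets the arrays to one overall level. Response groups and the pairing of arrays were taken from the labels.

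The table held 22277 probe sets, 62 of them controls. A single gene was listed for 19064, of which 19052 were matched to current gene names by gene number. Several genes were listed for 1043 and none for 2108. These were left out of the gene tests. In all, 52 sex-linked probe sets were left out of every gene and list test. The comparison of pairs of untreated arrays and the percentile of the filter on dim probe sets did include them. No detection calls were used. Signals under 1 (1.28% of values) were set to 1 before log2. Each of 11939 genes was represented by its probe set of highest mean. Genes under the 40th percentile of mean log2 signal, a signal of 47.8, were not tested, which left 8023 genes. The 2 untreated arrays sharing a label number were averaged after log2, so 20 samples entered the fits.

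The 3 comparisons, sensitive versus untreated, resistant versus untreated and sensitive versus resistant samples, were fitted together in limma 3.58.1 under R 4.3.3 (lmFit, eBayes with trend and robust). P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. SE values come from limma, and levels are geometric mean signals. Of 37 gene lists, the 30 with at least 5 tested members were tested with limma's camera (preset correlation 0.01), adjusted over the lists. Camera sets a list against the other genes tested, so higher or lower in camera is relative to those and not to 0. Camera with the correlation estimated per list and an exact permutation over samples of the list's mean z were run beside it. In splits of the samples that mixed the groups, camera with the preset correlation still called a median of 10 to 12 lists. A further adjustment over the members of each list alone is given as counts. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. The tests, lists, thresholds and alternatives were fixed before the data were examined, except where the text says otherwise. The genes named in each comparison are the 12 largest rises and the 12 largest falls past the threshold. Where fewer than 5 genes passed, the 5 smallest p in each direction are named too. Up to 4 members of smallest p are named from each list that passed or had a member past the threshold, along with markers of the sort and a fixed panel of activation genes.

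The fits were tested on simulated data made from the measured spreads, with 200 of 8023 genes changed, 50 each by log2 0.5, 1, 2 and 4. Genes were drawn independently of each other, and samples did not differ in RNA quality. The rates below therefore do not carry over to the measured data, in which genes move together. For sensitive versus untreated 8, 60, 92 and 100% of these were recovered, with 10 unchanged genes called. For resistant versus untreated 18, 68, 92 and 100% were recovered (10 unchanged called), and for sensitive versus resistant 10, 52, 90 and 98% (4 unchanged called). RNA quality was read from the 3' and 5' control probe sets of ACTB and GAPDH. Alternatives were log2 of the value plus 50, quantile normalization, median centring, no filter, a 60th percentile filter, the mean of a gene's probe sets, every probe set on its own, the pair as 2 samples and array weights. The others were the GIST marker mean or the 3' to 5' ratio as a covariate, plain eBayes, fits of only the 2 groups compared, and leaving out each sample in turn. Fits without the 2 sensitive samples of highest ratio, and without those and untreated sample 12, were added after seeing the data.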

Results

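Tumor-associated macrophages were isolated from freshly resected human gastrointestinal stromal tumors (GIST). These are sarcomas of the gut wall that are usually driven by the receptor kinase KIT and are treated with imatinib, an oral inhibitor of KIT. After enzymatic digestion, cells carrying KIT, CD3 or CD56 were removed with magnetic beads, and cells carrying CD14 were then kept. RNA from these cells was hybridized to Affymetrix 3' expression arrays, 21 in all. Of these, 12 came from untreated tumors, 5 from tumors sensitive to imatinib and 4 from tumors resistant to it. The study asked how imatinib therapy affects these macrophages, including their M1-type (inflammatory) or M2-type (tissue-repair) activation. A pair of the untreated arrays carried the same number in its labels. The Spearman rho of this pair was 0.983, against 0.891 to 0.958 for the 65 other pairs of untreated arrays. The SD of its log2 differences was 0.22, against at least 0.59 in the other pairs. The pair was averaged and counted as 1 sample, which left n = 11 untreated, 5 sensitive and 4 resistant samples.

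Each array had a trimmed mean signal of about 500, and its median signal lay between 93.2 and 132. Of 11939 genes with a probe set of their own, 8023 were bright enough to be tested. The number of arrays, 4 in the smallest group, limits the precision of every value. The labels speak of separate tumors, but p-values measure the spread between these samples.

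The markers used for the sort did not differ past the threshold between groups. CD14, the receptor used for positive selection, had a geometric mean signal of 13167 in untreated, 11842 in sensitive and 15031 in resistant samples. Its log2 differences from untreated samples were -0.15 ± 0.21 (SE, adjusted p = 0.633) and 0.19 ± 0.23 (adjusted p = 0.804). KIT, the tumor cell marker that was selected against, stood at 426, 176 and 272 (adjusted p = 0.191 and 0.801). The T cell receptor chains CD3D and CD3E had signals of 181 and 52.6 in untreated samples. NCAM1, which encodes CD56, was too dim to be tested, with a signal of 46 in untreated samples. Untreated sample 12 stood apart from the other untreated samples. Its mean log2 signal over the GIST marker list was 11.04, against 7.11 to 9.09 in the others. Over the macrophage identity list its mean was 10.56, against 11.40 to 12.14.

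RNA quality differed between groups. The log2 ratio of signals at the 3' and 5' ends of the ACTB and GAPDH control transcripts rises when RNA is degraded. It was 1.92 ± 0.20 (SD, n = 11) in untreated, 2.57 ± 0.50 (n = 5) in sensitive and 1.91 ± 0.33 (n = 4) in resistant samples. Sensitive samples exceeded untreated samples by 0.65 (2-sided exact permutation p = 0.000916 over 4368 arrangements), whereas resistant samples differed from them by -0.01 (exact permutation p = 0.952). Sensitive samples 4 and 5 had the highest ratios, 2.91 and 3.28. Sensitive samples 1 to 3, at 2.21 to 2.23, lay within the untreated range of 1.64 to 2.27, but above every untreated sample except sample 7.

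Macrophages from imatinib-sensitive tumors (n = 5) were first set against those of untreated tumors (n = 11). Per the labels these are separate tumors, so rises and falls below are differences between groups. The design cannot separate therapy from other differences between the groups, such as that in RNA quality. CXCL5, a chemokine that attracts neutrophils, rose from a geometric mean signal of 18.9, under the filter on dim probe sets, to 1019.5 (log2 difference 5.75, SE 1.40, adjusted p = 0.009), and the size of that rise is uncertain. TNFAIP6, a matrix-binding protein made during inflammation, rose from 122 to 2506 (log2 difference 4.36, SE 0.86, adjusted p = 0.00377). AQP9, a water and glycerol channel of myeloid cells, rose from 201 to 3357 (log2 difference 4.06, SE 0.83, adjusted p = 0.00412). CX3CR1, the fractalkine receptor of monocytes and tissue macrophages, fell from 4344 to 603 (log2 difference -2.85, SE 0.41, adjusted p = 0.0015), and the ranges of the groups did not overlap. By limma, 1931 of 8023 genes passed, 442 higher and 1489 lower, and 2991 had an unadjusted p under 0.05.

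With CXCL5, TNFAIP6 and AQP9, the 12 genes of largest estimated rise were MGAM (4.39 ± 1.30, log2 difference ± SE), CHI3L1 (4.13 ± 1.04), KCNJ15 (3.96 ± 1.02), S100P (3.71 ± 1.21), EREG (3.69 ± 0.94), CCL20 (3.46 ± 0.84), FCAR (3.38 ± 0.78), PI3 (3.36 ± 0.83) and CYP4F3 (3.30 ± 0.90). The adjusted p of the 12 ranged from 0.00377 to 0.0328. All 5 sensitive samples lay above the untreated median, except for MGAM, S100P and CYP4F3, where 4 of 5 did. The untreated signals of CXCL5, MGAM, KCNJ15, PI3 and CYP4F3 lay under 47.8, the filter on dim probe sets, so the size and rank of these rises are uncertain. The largest fall was in HLA-DQA1, an MHC class II chain (log2 difference -4.90, SE 1.75, adjusted p = 0.0478), a gene that varies between people and whose log2 signal had an SD of 3.49 within untreated samples. HPGDS, a prostaglandin D2 synthase, fell from 1207 to 174 (log2 difference -2.79, SE 0.74, adjusted p = 0.0129). DNASE1L3, a secreted DNase, fell from 3184 to 436 (log2 difference -2.87, SE 0.89, adjusted p = 0.0267). The other large falls were those of WNT5B (-3.37 ± 0.76), ASPM (-2.94 ± 0.66), S100B (-2.93 ± 0.79), TRIM36 (-2.70 ± 0.66), OIP5 (-2.65 ± 0.65), ABCB4 (-2.62 ± 0.66), ELAVL4 (-2.60 ± 0.38) and LAMP5 (-2.51 ± 0.72). These 8 genes had signals of 9.65 to 36.8 in sensitive samples, under the filter. All 5 sensitive samples lay below the untreated median in the 12 falls, except for S100B, where 4 of 5 did.

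Genes of neutrophils and of newly recruited monocytes rose. Of 14 neutrophil markers on the array, 6 were bright enough to be tested. All 6 passed the gene test as higher, and 6 did when adjusted over the list alone (median log2 difference 2.59). Among them were VNN2 (log2 difference 2.83, SE 0.67, adjusted p = 0.00816), the chemokine receptor CXCR2 (2.65 ± 0.83, adjusted p = 0.0272) and the Fc receptor FCGR3B (2.53 ± 0.65, adjusted p = 0.0115). Of 17 monocyte markers, 12 rose, 1 fell and 4 did not pass, with a median of 2.19 (13 higher and 3 lower when adjusted over the list alone). TREM1, an activating receptor of monocytes and neutrophils, rose from 226 to 1883 (log2 difference 3.06, SE 0.67, adjusted p = 0.00582). The formyl peptide receptor FPR1 (2.41 ± 0.58), the G-CSF receptor CSF3R (2.01 ± 0.47), which is on both lists, and the lysozyme gene LYZ (1.20 ± 0.24) rose as well (adjusted p 0.00377 to 0.00868). Both lists passed camera (adjusted p = 7.3e-06 and 6.51e-07), and neither did with an estimated correlation (adjusted p = 0.439 for both). The exact permutation over samples kept the neutrophil list (adjusted p = 0.0298) and not the monocyte list (adjusted p = 0.0865). The neutrophil median was 2.28 without sensitive samples 4 and 5 and 2.57 with the ratio as a covariate, and the monocyte median 1.84 without sensitive samples 4 and 5 and 2.00 with the ratio as a covariate. Without those 2 samples 0 neutrophil and 2 monocyte markers passed the gene test as higher. The neutrophil list mean of sensitive sample 1 (7.53) lay within the untreated range of 6.59 to 9.52.

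Of 22 NF-kB target genes, 10 rose and 0 fell, with a median of 0.69 (15 higher when adjusted over the list alone). CCL20, which attracts lymphocytes and dendritic cells, rose from 549 to 6054 (adjusted p = 0.00868). The neutrophil chemokines CXCL3 (1.37 ± 0.34, adjusted p = 0.0101) and CXCL2 (0.97 ± 0.22, adjusted p = 0.00627) rose too. In the hypoxia and glycolysis list 6 of 19 genes rose and 0 fell, with a median of 0.46 (8 higher when adjusted over the list alone). They included the vasodilator peptide adrenomedullin (ADM, log2 difference 2.55, SE 0.48, adjusted p = 0.00311), the glucose transporter SLC2A3 (1.71 ± 0.58), NDRG1 (1.45 ± 0.40) and PFKFB3 (1.40 ± 0.43). Of 18 immediate-early and heat-shock genes 4 rose, also when adjusted over the list alone (median 0.35). These were CCN1 (2.47 ± 0.64), EGR1 (0.68 ± 0.21), JUN (0.40 ± 0.11) and DUSP1 (0.43 ± 0.14), and DUSP1 came to -0.17 when its probe sets were averaged. The 3 lists passed camera (adjusted p = 1.01e-09, 4.5e-06 and 0.00016), and none did with an estimated correlation (adjusted p = 0.439 for each). The exact permutation over samples kept the NF-kB list (adjusted p = 0.0298) and not the hypoxia (0.1) or immediate-early list (0.155). The NF-kB median was 0.62 without sensitive samples 4 and 5 and 0.40 with the ratio as a covariate. The hypoxia median was 0.67 without sensitive samples 4 and 5 and 0.74 with the ratio as a covariate, and the immediate-early median 0.12 without sensitive samples 4 and 5 and -0.02 with the ratio as a covariate. Medians moved by over 1.5 times for hypoxia (0.22 without sensitive sample 3) and immediate-early genes (0.20 without sensitive sample 5) when 1 sample was left out.

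Genes of lipid handling, lysosomes and matrix rose in part. The apolipoprotein APOC1 (log2 difference 2.53, SE 0.69, adjusted p = 0.0153), the lysosomal glycoprotein GPNMB (1.94 ± 0.57) and the lipid droplet protein PLIN2 (1.64 ± 0.40) were the 3 of 20 lipid genes that rose. In the lysosome list 5 of 16 genes rose, including the protease CTSD (log2 difference 1.57, SE 0.36, adjusted p = 0.00742), CD63 (0.59 ± 0.16), CTSB (0.52 ± 0.18) and PSAP (0.47 ± 0.16). In the matrix and angiogenesis list 4 of 19 genes rose and 1 fell. Thrombospondin 1 (THBS1, 2.27 ± 0.64), MMP19 (2.17 ± 0.62) and the urokinase receptor PLAUR (1.60 ± 0.45) were among the rises, and TGFBI fell (-0.48 ± 0.15). Adjusted over the list alone, 3, 6 and 4 genes of these lists rose. Medians were 0.55, 0.34 and 0.38, and camera gave adjusted p = 0.000248, 0.000248 and 0.00242 (adjusted p = 0.439, 0.531 and 0.439 with an estimated correlation). Medians moved by over 1.5 times for lipid handling (1.01 without sensitive sample 2 and 0.22 without sensitive sample 3), lysosome (0.18 without sensitive sample 3) and matrix (0.58 without sensitive sample 1) when 1 sample was left out. Without sensitive samples 4 and 5 the medians were 0.69, 0.56 and 0.65, and with the 3' to 5' ratio as a covariate 0.71, 0.41 and 0.56. Iron and heme genes did not pass as a list (median 0.61, adjusted p = 0.0519). Of its 10 genes the metal transporter SLC11A1 (log2 difference 3.27, SE 0.64, adjusted p = 0.00374) and the ferritin chain FTL (0.56 ± 0.19) rose, and NCOA4 (-0.43 ± 0.13) fell (3 higher and 1 lower when adjusted over the list alone).

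Cell division genes fell as a group. In sensitive samples 22 of 23 were lower, and 23 were when adjusted over the list alone (median log2 difference -1.77). TOP2A, the DNA topoisomerase of dividing cells, fell from 682 to 138 (log2 difference -2.31, SE 0.44, adjusted p = 0.00336; 5 of 5 samples under the untreated median). The mitotic kinase CDK1 fell from 1015 to 211 (log2 difference -2.27, SE 0.45, adjusted p = 0.00377). The replication helicase subunits MCM2 (-2.15 ± 0.45) and MCM5 (from 1044 to 523) fell as well (adjusted p = 0.00446 and 0.00348). Camera gave an adjusted p of 6.88e-09 (adjusted p = 0.439 with an estimated correlation), and the exact permutation over samples an adjusted p of 0.0298. The list mean was lowest in sensitive samples 4 and 5, at 5.70 and 5.78, the samples with the highest 3' to 5' ratios. It was 6.65 to 8.26 in sensitive samples 1 to 3 and 7.15 to 9.58 in untreated samples. Without samples 4 and 5 the median was -0.92 and 5 genes were lower, and with the ratio as a covariate it was -0.84 and 0 genes were lower.

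**Figure D1:**
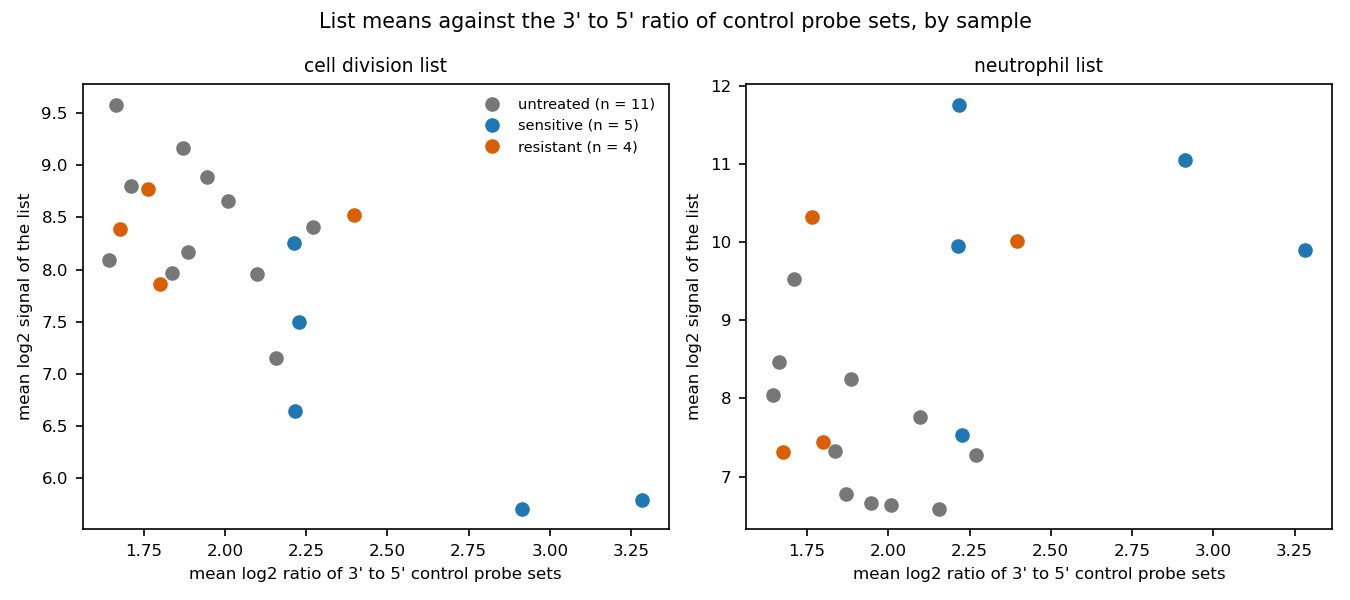
Mean log2 signal of the 23 tested cell division genes (left) and the 6 tested neutrophil genes (right) in each of 20 samples, against the mean log2 ratio of 3' to 5' control probe sets, with 1 point per sample. Sensitive samples 4 and 5, at ratios of 2.91 and 3.28, have the lowest cell division means, while their neutrophil means of 11.04 and 9.89 lie within the range of sensitive samples 1 to 3 (7.53 to 11.76).

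The lists of macrophage identity, of complement and uptake of dying cells and of macrophage transcription factors did not pass, and single members moved both ways. CSF1R, the receptor for the macrophage growth factor CSF1, fell from 5788 to 2187 (log2 difference -1.40, SE 0.25, adjusted p = 0.00264). The transcription factor MAF fell from 7869 to 2253 (log2 difference -1.80, SE 0.31, adjusted p = 0.00235), and AXL, a receptor for dying cells, from 3972 to 1161 (log2 difference -1.77, SE 0.37, adjusted p = 0.00447). The complement chains C1QA (-0.92 ± 0.26) and C1QB (-0.97 ± 0.28), IRF8 (-0.98 ± 0.28) and CD4 (-0.93 ± 0.24) fell too, and CD4 came to 0.016 when its probe sets were averaged. The integrin ITGAX (1.37 ± 0.30), complement factor D (CFD, 1.18 ± 0.35) and the transcription factor STAT3 (0.33 ± 0.12) rose. In the macrophage identity list 3 of 14 genes rose and 3 fell, and in the list of complement and uptake of dying cells 1 of 17 rose and 5 fell. In the transcription factor list 2 of 18 rose and 2 fell. Adjusted over the list alone, 3 and 3, 1 and 6, and 2 and 2 genes of these lists rose and fell (camera adjusted p = 0.508, 0.656 and 0.267). Without sensitive samples 4 and 5 their medians were 0.10, -0.39 and 0.01, against -0.09, -0.43 and 0.06 with all samples, and with the ratio as a covariate 0.11, -0.39 and 0.08. Past the gene test but named only after their values were seen were LAMP1 in the lysosome and TIMP1 in the matrix list, MARCO and AIF1 in the identity list, and STAB1 and ITGB5 in the complement list.

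Of 12 MHC class II genes 5 fell and 0 rose (7 lower when adjusted over the list alone, camera adjusted p = 0.0832), including HLA-DPB1 (-0.70 ± 0.20), HLA-DMA (-0.73 ± 0.22), HLA-DQB1 (-1.01 ± 0.29), the class II transactivator CIITA (-1.03 ± 0.32) and HLA-DQA1, named above. Of 26 interferon-induced genes 8 fell and 0 rose (12 lower and 1 higher when adjusted over the list alone, camera adjusted p = 0.0832). IFIT1 (log2 difference -1.45, SE 0.48, adjusted p = 0.0349), MX1 (-1.18 ± 0.39), OAS2 (-1.14 ± 0.30) and XAF1 (-0.87 ± 0.25), which act in antiviral defense or cell death, were among them. The class II median of -0.72 was -0.45 without sensitive samples 4 and 5 and -0.52 with the ratio as a covariate. The interferon median of -0.54 was -0.71 without sensitive samples 4 and 5 and -0.80 with the ratio as a covariate. In these 2 fits interferon genes passed camera as lower (adjusted p = 0.000541 and 0.000954), as they did without a filter (0.00794) and with median centring (0.041). Class II genes passed camera as lower with quantile normalization (adjusted p = 0.000589), without a filter (0.0145), with averaged probe sets (0.0155) and with array weights (0.0459).

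With all samples and no covariate, neither activation list passed camera. Of 20 M1-type markers 3 rose and 1 fell (3 and 1 when adjusted over the list alone, camera adjusted p = 0.171). Interleukin 6 (IL6) rose from 1077 to 4662 (log2 difference 2.11, SE 0.71, adjusted p = 0.0381), and SOCS3 (1.76 ± 0.52) and IRF1 (1.05 ± 0.36) rose. The T cell chemoattractant CXCL10 fell from 6558 to 1694 (log2 difference -1.95, SE 0.67, adjusted p = 0.0417). Of 26 M2-type markers 3 rose and 7 fell (5 and 9 when adjusted over the list alone, camera adjusted p = 0.603). The mannose receptor MRC1 fell from 13805 to 6371 (log2 difference -1.12, SE 0.22, adjusted p = 0.00336; 5 of 5 samples). The lectin CD209 (-2.43 ± 0.41) and the cytokine TGFB1 (-0.51 ± 0.17) fell (adjusted p = 0.00222 and 0.0365), whereas the chemokine CCL18 rose from 823 to 4119 (log2 difference 2.32, SE 0.80, adjusted p = 0.0421). The transcription factor CEBPB rose by 0.74 (SE 0.23, adjusted p = 0.0274; 4 of 5 samples). CD163 (-0.18 ± 0.20), MSR1 (-0.46 ± 0.40), CD86 (-0.32 ± 0.24), IL10 (-0.03 ± 0.41), IL1B (0.74 ± 0.30), TNF (0.09 ± 0.36) and IRF4 (-0.51 ± 0.35) did not pass (adjusted p 0.0763 to 0.973), and CCL22 and IL12B were too dim to be tested. The M1-type median of -0.12 was 0.10 without sensitive samples 4 and 5 and 0.17 with the ratio as a covariate, and the M2-type median of -0.62 was -0.40 without sensitive samples 4 and 5 and -0.26 with the ratio as a covariate. In these 2 fits the M1-type list passed camera as higher (adjusted p = 0.0125 and 0.048).

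Markers of other cell types were mixed. Smooth muscle and fibroblast lists passed camera as higher (medians 1.19 and 0.87, adjusted p = 0.00237 and 0.00654), and not with an estimated correlation (adjusted p = 0.558 and 0.692). Of their 9 and 12 genes only TAGLN (2.08 ± 0.72) passed the gene test, and 0 did when adjusted over the list alone. Without sensitive samples 4 and 5 their medians were 0.19 and 0.54, and with the ratio as a covariate 0.14 and 0.17. Leaving out 1 sample ended the camera call (median in brackets) of fibroblast markers (0.62 without sensitive sample 1). It moved the median by over 1.5 times for smooth muscle (1.82 without sensitive sample 3 and 0.79 without sensitive sample 5) and fibroblast markers (1.44 without sensitive sample 3 and 0.55 without sensitive sample 5). GIST markers did not pass as a list (median -0.35, adjusted p = 0.603), and PROM1 (-2.37 ± 0.67) and PRKCQ (-1.55 ± 0.46) fell. Endothelial, dendritic cell, T cell and NK cell lists did not pass (medians 0.34, -0.99, -0.26 and -0.39, adjusted p = 0.0618, 0.54, 0.603 and 0.785). In these 4 lists the lipid-presenting molecule CD1C (-1.92 ± 0.62) was the 1 gene past the gene test. Of the 7 lists with fewer than 5 tested members, KRT18 (1.64 ± 0.35) in the epithelial and NRGN (1.39 ± 0.46) in the platelet list rose. HPGDS in the mast cell list and S100B and ELAVL4 in the list of glia and neurons, all named above, fell, and 0 genes of the B and plasma cell, hepatocyte and erythroid lists passed.

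MHC class I and ribosomal protein lists passed camera with medians of 0.19 and 0.10 (adjusted p = 0.048 and 0.0167, and 0.558 and 0.806 with an estimated correlation). HLA-C (0.44 ± 0.15) was the 1 member of either past the gene test. The ribosomal median turned to -0.17 after quantile normalization, to -0.29 with the 3' to 5' ratio as a covariate and to -0.11 without sensitive samples 4 and 5. Leaving out 1 sample ended the camera call (median in brackets) of MHC class I (0.17 without untreated sample 3, 0.19 without untreated sample 5, 0.17 without untreated sample 8, 0.15 without the averaged pair, 0.23 without untreated sample 12, 0.27 without sensitive sample 1, 0.13 without sensitive sample 2, 0.19 without resistant sample 1 and 0.19 without resistant sample 3) and ribosomal proteins (-0.086 without sensitive sample 5). It moved the median by over 1.5 times for MHC class I (0.29 without sensitive sample 3 and 0.11 without sensitive sample 5) and ribosomal proteins (0.19 without sensitive sample 1). Oxidative phosphorylation, the unfolded protein response, cholesterol synthesis and T cell chemoattractants did not pass as lists. In the first, 4 of 27 genes fell, NDUFB5 (-0.41 ± 0.08), NDUFV2 (-0.53 ± 0.11), ATP5F1A (-0.28 ± 0.10) and ATP5PO (-0.27 ± 0.08). In the second, 3 of 16 fell, HERPUD1 (-0.67 ± 0.23), PDIA6 (-0.48 ± 0.16) and CANX (-0.36 ± 0.12). In the third, 2 of 11 fell, SQLE (-0.66 ± 0.21) and MSMO1 (-0.65 ± 0.20), and in the fourth 1 of 9, CXCL10. Their camera adjusted p were 0.603, 0.418, 0.86 and 0.361. Median and mean, or median and test, differed in sign in 5 lists. Median and mean were 0.04 and -0.12 for cholesterol synthesis, 0.06 and -0.04 for transcription factors and -0.09 and 0.15 for macrophage identity. M1-type markers (-0.12 and -0.01) and T cell markers (-0.26 and -0.20) had a negative median and mean but ranked as higher in camera. The median log2 difference of all genes tested was -0.14 in this comparison. A list near or under 0 can therefore still rank as higher in camera.

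**Figure D2:**
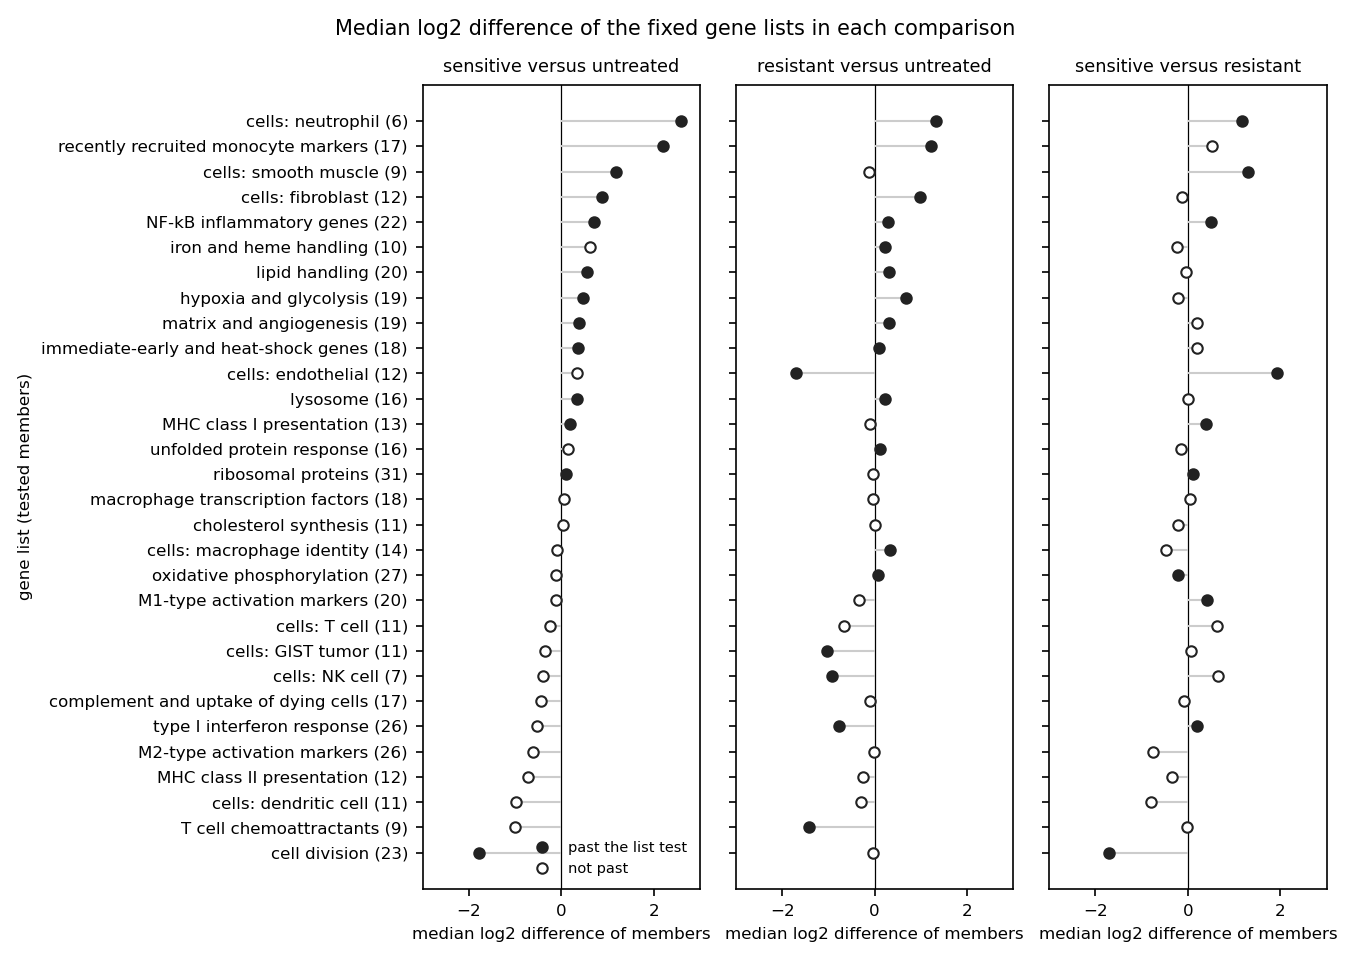
Median log2 difference of the tested members of each of 30 fixed gene lists (y axis, number of tested members in brackets) in the 3 comparisons. Filled circles passed camera at an adjusted p under 0.05 with a preset correlation (13, 18 and 10 lists from left to right), open circles did not, and 0 lists passed with an estimated correlation.

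Fewer genes passed in sensitive versus untreated samples when RNA quality was taken into account. With the 3' to 5' ratio as a covariate 93 genes passed, 26 higher and 67 lower, of which 77 were among the 1931. The median log2 difference of the 1489 lower genes went from -0.67 to -0.50 and their median SE from 0.18 to 0.23. For the 442 higher genes the median went from 1.04 to 0.81 and the median SE from 0.30 to 0.39. Of the genes named here, AXL (-2.11) and CX3CR1 (-2.52) still passed. Without sensitive samples 4 and 5, a choice made after seeing the data, 550 genes passed, 117 higher and 433 lower (470 shared). That fit held fewer sensitive samples, so lost power and RNA quality cannot be told apart in its lower count. The count was 1253 with array weights, 1268 without sensitive sample 2 and 1165 without sensitive sample 5. Of the 13 lists past camera, 3 passed the exact permutation and 0 passed with an estimated correlation (3 at an unadjusted p under 0.05). With the ratio as a covariate the camera calls of MHC class I, immediate-early genes, fibroblast markers and smooth muscle ended, that of ribosomal proteins turned, and M1-type markers, interferon genes and iron and heme handling passed. Leaving out sensitive samples 4 and 5 ended the calls of ribosomal proteins and smooth muscle. Other settings ended calls of MHC class I with quantile normalization, with log2 of the value plus 50, with averaged probe sets and with the GIST marker covariate and of MHC class I and ribosomal proteins without a filter, and that of ribosomal proteins with quantile normalization turned. MHC class II and interferon genes were gained as lower in the settings named above. Iron and heme handling was gained with median centring, without a filter, with the 60th percentile filter and with the pair as 2 samples. Endothelial markers were gained as higher with array weights and with the GIST marker covariate.

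Of the 102 genes named here that passed, 46 passed in each of 20 fits that left out 1 sample, among them CX3CR1, CSF1R, MAF, MRC1, TOP2A, CXCL5, TNFAIP6, AQP9 and TREM1. The fit without sensitive sample 5 lost 42 of the calls, that without sample 4 34, that without sample 2 32 and that without sample 3 30, while that without untreated sample 6 lost 20. HLA-DQA1 was lost in 17 of the 20 fits, STAT3 in 14, CCL18, CXCL10, IRF1 and DUSP1 in 10 each, IL6 in 9, SLC2A3 in 8, and CEBPB in 4.

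Macrophages from imatinib-resistant tumors (n = 4) were next compared with those of untreated tumors (n = 11). By limma 1 gene passed, IL3RA, the interleukin 3 receptor chain found on plasmacytoid dendritic cells and basophils. Its signal fell from 173 to 15.3, under the filter on dim probe sets (log2 difference -3.50, SE 0.55, adjusted p = 0.028; 4 of 4 samples under the untreated median). In all, 850 genes had an unadjusted p under 0.05. The smallest p among higher genes were those of NDUFB3 (1.04 ± 0.22), NCLN (1.10 ± 0.25), SAP30 (1.25 ± 0.29), PLIN2 (1.73 ± 0.44) and HOXC6 (1.99 ± 0.53). Among lower genes other than IL3RA they were those of NMT2 (-1.21 ± 0.25), RAI2 (-3.31 ± 0.71), CMTR1 (-0.65 ± 0.14) and DDB2 (-0.88 ± 0.19). None of these 9 passed (adjusted p 0.178 to 0.312). The IL3RA call was lost in 12 of the 20 fits that left out 1 sample (adjusted p 4.67e-06 to 0.309 over the 20), namely those without untreated sample 1, 3, 4, 6, 7, 11, 12 or the averaged pair 9 and 10, or without any of the 4 resistant samples. Without sensitive sample 2, 2 genes passed.

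As lists, hypoxia and monocyte genes ranked higher in resistant samples by camera, although neither list passed the exact permutation (adjusted p = 0.0806 and 0.209). The mean 3' to 5' ratio of these samples was close to that of untreated samples, but resistant sample 2 (2.40) exceeded every untreated sample. All 19 hypoxia and glycolysis genes had log2 differences above 0 (median 0.68), and 12 passed when adjusted over the list alone. ADM stood at 5091 against 1295 (log2 difference 1.98, SE 0.52, adjusted p = 0.312), ENO1 at 0.99 ± 0.29 and PGK1 at 0.62 ± 0.21. Monocyte genes had a median of 1.23, with EREG at 2.76 ± 1.02, VCAN at 2.24 ± 0.88 and THBS1 at 1.99 ± 0.70. Resistant samples 1 and 2 had list means above the untreated range for hypoxia genes (11.75 and 12.28 against 10.12 to 11.49). They did so for monocyte genes too (11.81 and 11.98 against 8.11 to 11.31). Resistant samples 3 and 4 lay within it (11.35 and 11.04 for hypoxia, 10.62 and 10.25 for monocyte genes). Neutrophil genes had a median of 1.32, with FCGR3B at 1.42 ± 0.71. The neutrophil list mean was 10.32 and 10.02 in resistant samples 1 and 2 and 7.31 and 7.45 in samples 3 and 4, against 6.59 to 9.52 in untreated samples, so 2 of 4 samples carried the difference. In these 3 lists 0 genes passed over all genes, and 0 monocyte or neutrophil genes did when adjusted over the list alone. Lipid handling (median 0.30, osteopontin SPP1 at 3.11 ± 1.20), lysosome (0.23, CTSD at 0.83 ± 0.39), iron and heme handling (0.22, heme oxygenase HMOX1 at 1.92 ± 0.54) and macrophage identity (0.32, the scavenger receptor MARCO at 2.39 ± 1.12) were higher too. In them 1, 0, 1 and 0 genes passed when adjusted over the list alone. Camera gave adjusted p = 2.1e-13, 1.26e-08, 0.000658, 0.000118, 8.29e-05, 0.00216 and 0.000658 for the 7 lists in that order, and adjusted p of 0.308 to 0.347 with an estimated correlation. Medians moved by over 1.5 times for neutrophil genes (0.71 without resistant sample 1), lipid handling (0.20 without resistant sample 1), lysosome (0.36 without resistant sample 4), iron and heme handling (0.43 without resistant sample 4) and macrophage identity (0.20 without untreated sample 12) when 1 sample was left out. NF-kB genes (0.28, CCL20 at 2.23 ± 0.91), fibroblast markers (0.97, COL1A1 at 1.91 ± 1.02), immediate-early genes (0.09), matrix genes (0.30), oxidative phosphorylation (0.06) and the unfolded protein response (0.11) passed as higher as well. Their camera adjusted p were 0.00127 to 0.0147, and 0.308 to 0.438 with an estimated correlation. Leaving out 1 sample ended the camera call (median in brackets) of NF-kB genes (0.13 without resistant sample 1), fibroblast markers (0.44 without resistant sample 4), immediate-early genes (0.046 without untreated sample 3, -0.0078 without resistant sample 2 and 0.075 without resistant sample 3), matrix genes (0.19 without resistant sample 1 and 0.21 without resistant sample 2) and the unfolded protein response (0.094 without resistant sample 1). It moved the median by over 1.5 times for NF-kB genes (0.18 without resistant sample 2 and 0.50 without resistant sample 4), immediate-early genes (0.047 without untreated sample 6 and 0.26 without resistant sample 4), oxidative phosphorylation (0.11 without resistant sample 2 and 0.015 without resistant sample 4) and the unfolded protein response (0.056 without untreated sample 11 and 0.058 without resistant sample 3).

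As lists, interferon-induced and endothelial genes ranked lower in resistant samples by camera, although 0 genes of either passed over all genes by limma and neither list passed the exact permutation (adjusted p = 0.0806 and 0.209). All 26 interferon genes had log2 differences under 0 (median -0.76), and 7 passed when adjusted over the list alone. IFI27 stood at 208 against 1569 (log2 difference -2.91, SE 0.68, adjusted p = 0.232), IFI44L at -1.55 ± 0.52 and the RNA-sensing kinase EIF2AK2 at -0.95 ± 0.24. All 12 endothelial genes were also under 0 (median -1.71, 9 past when adjusted over the list alone). Von Willebrand factor (VWF) stood at 601 against 3042 (log2 difference -2.34, SE 0.77, adjusted p = 0.313) and the sialomucin EMCN at -2.84 ± 0.76. T cell chemoattractants (median -1.43, CCL19 at -2.09 ± 0.74), NK cell genes (-0.91, KLRB1 at -2.05 ± 0.96) and GIST markers (-1.02, CD34 at -1.22 ± 0.50) were lower, with 0 genes past when adjusted over the list alone. Without sensitive samples 4 and 5 and untreated sample 12, the sample of highest GIST markers, the GIST median was -0.71 and the endothelial median -1.57. Camera gave adjusted p = 1.19e-10, 1.05e-06, 0.00216, 0.0147 and 0.0147 for these 5 lists in that order. With an estimated correlation the adjusted p were 0.308 to 0.453. Leaving out 1 sample ended the camera call (median in brackets) of T cell chemoattractants (-1.47 without resistant sample 4), NK cell genes (-0.57 without resistant sample 3 and -1.07 without resistant sample 4) and GIST markers (-0.79 without resistant sample 3). It moved the median by over 1.5 times for T cell chemoattractants (-2.21 without resistant sample 3). Resistant sample 3 had the lowest list means of the 4 resistant samples for NK cell genes (4.58, the others 6.22 to 7.19) and GIST markers (6.35, the others 7.07 to 8.42). The other 12 lists did not pass (adjusted p 0.102 to 0.934), with medians of -0.34 for M1-type and -0.01 for M2-type markers. M1-type markers passed camera as lower with quantile normalization (adjusted p = 0.0224), median centring (0.0208), the GIST marker covariate (0.0287) and only the 2 groups compared (0.049). Median and mean differed in sign for M2-type markers (-0.01 and 0.02) and transcription factors (-0.04 and 0.01). Complement (-0.10 and -0.09), cell division (-0.04 and -0.05), ribosomal protein (-0.04 and -0.02) and smooth muscle genes (-0.12 and -0.23) had a negative median and mean but ranked as higher in camera.

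None of the activation panel passed in resistant samples by limma, with adjusted p of 0.395 to 0.974. MRC1 stood at -0.18 ± 0.23, CD163 at 0.29 ± 0.22, MSR1 at 0.28 ± 0.43, CCL18 at -0.17 ± 0.87, IL10 at 0.73 ± 0.45 and TGFB1 at -0.35 ± 0.18. IL1B stood at 0.27 ± 0.32, IL6 at 0.29 ± 0.77, TNF at -0.26 ± 0.39, CXCL10 at -1.43 ± 0.73 and CD86 at 0.15 ± 0.26. IRF4 stood at -0.27 ± 0.38 and CEBPB at 0.61 ± 0.25. Of the 18 lists past camera, 13 higher and 5 lower, 0 passed the exact permutation over samples (smallest adjusted p 0.0806) and 0 passed with an estimated correlation (2 at an unadjusted p under 0.05). Other settings ended camera calls of immediate-early genes, matrix genes, oxidative phosphorylation and the unfolded protein response with quantile normalization, of matrix genes with median centring, of the unfolded protein response without a filter, of GIST markers with the 60th percentile filter, of GIST markers and NK cell genes with array weights and without sensitive samples 4 and 5 and untreated sample 12 and of matrix genes, macrophage identity and NK cell genes with the GIST marker covariate. Besides M1-type markers, quantile normalization added MHC class II, MHC class I and ribosomal proteins as lower, and median centring added T cell markers (median -0.54). The GIST marker covariate added cell division as lower and cholesterol synthesis and smooth muscle as higher.

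Sensitive (n = 5) and resistant samples (n = 4) were compared directly, which also tests whether their differences from untreated samples differ. E-selectin (SELE), an adhesion molecule of activated endothelium, was higher in sensitive samples, at 1369.5 against 8.52 (log2 difference 7.33, adjusted p = 0.0405), the second under the filter on dim probe sets. The prostaglandin D2 synthase PTGDS stood at 1747 against 107 (log2 difference 4.03, SE 0.85, adjusted p = 0.0487), and IL3RA was higher (log2 difference 3.47, SE 0.63, adjusted p = 0.0284). RNF126P1 (1.89 ± 0.31), ASB1 (1.66 ± 0.32), LXN (1.38 ± 0.23) and HIVEP1 (1.18 ± 0.22) were the other higher genes (adjusted p 0.0284 to 0.0293). Lower in sensitive samples were the kinase PRKCA (262 against 847; log2 difference -1.69, SE 0.30, adjusted p = 0.0284), the integrin chain ITGA4 (-1.65 ± 0.32) and the lysophosphatidic acid receptor LPAR6 (-1.56 ± 0.27). The rest of the 12 largest falls were KIF18B (-1.53 ± 0.31), CAMK1 (-1.17 ± 0.22), PCCA (-1.03 ± 0.19), RCC1 (-0.94 ± 0.19), EIPR1 (-0.92 ± 0.18), NUP43 (-0.89 ± 0.17), GATD3 (-0.88 ± 0.17), CBX1 (-0.84 ± 0.17) and CEP63 (-0.84 ± 0.16), with adjusted p of 0.0284 to 0.0405. By limma 21 genes passed, 7 higher and 14 lower, and 1863 had an unadjusted p under 0.05. The count rested on single samples. It was 802 without sensitive sample 1, 299 without sensitive sample 3 and 122 without untreated sample 12. It was 13 without resistant sample 1, 9 without sensitive sample 2, 4 without resistant sample 2, and 0 without sensitive sample 4 or 5 or resistant sample 3 or 4.

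Cell division genes were lower in sensitive than in resistant samples as a list (median -1.71). None of 23 passed over all genes and 19 did when adjusted over the list alone, with CDK1 at 211 against 958 (log2 difference -2.19, SE 0.56, adjusted p = 0.0661) and TOP2A at -2.16 ± 0.55. The cell division median was -0.89 without sensitive samples 4 and 5 and -0.71 with the ratio as a covariate. Endothelial genes were higher (median 1.92, 9 of 12 past when adjusted over the list alone), with VWF at 5565 against 601 (log2 difference 3.21, SE 0.88, adjusted p = 0.0746) and the cadherin CDH5 at 1.90 ± 0.59. Their median was 1.34 without sensitive samples 4 and 5 and 1.32 with the ratio as a covariate. Camera gave adjusted p = 3.86e-10 and 2.17e-07 (adjusted p = 0.83 for both with an estimated correlation). NF-kB genes (median 0.50, RELB at 0.85 ± 0.24), M1-type markers (0.41, IRF1 at 1.42 ± 0.45), interferon genes (0.20, IFI27 at 2.86 ± 0.78) and neutrophil genes (1.16, VNN2 at 1.66 ± 0.84) were higher. So were smooth muscle markers (1.31, MYH11 at 3.43 ± 1.32), MHC class I (0.38, the peptide transporter TAP1 at 0.96 ± 0.34) and ribosomal proteins (0.11), and oxidative phosphorylation was lower (-0.21). With the ratio as a covariate the medians of these 8 lists in that order were 0.28, 0.52, -0.15, 1.17, 0.26, 0.15, -0.26 and -0.17. Without it they had camera adjusted p of 6.06e-05 to 0.0464 (adjusted p = 0.83 for each with an estimated correlation). Adjusted over the list alone, 1 interferon gene passed and 0 genes of the other 7 lists did. Leaving out 1 sample ended the camera call (median in brackets) of M1-type markers (0.19 without sensitive sample 1, 0.33 without sensitive sample 2 and 0.27 without resistant sample 4), interferon genes (0.14 without sensitive sample 1, -0.048 without sensitive sample 4 and 0.027 without resistant sample 1), neutrophil genes (0.75 without sensitive sample 2, 0.62 without resistant sample 3 and 0.55 without resistant sample 4), MHC class I (0.30 without sensitive sample 2 and 0.25 without resistant sample 4), ribosomal proteins (0.11 without untreated sample 2, 0.11 without untreated sample 5, 0.11 without untreated sample 8, 0.11 without untreated sample 12, 0.14 without sensitive sample 2, -0.063 without sensitive sample 5, 0.055 without resistant sample 1 and 0.081 without resistant sample 3) and oxidative phosphorylation (-0.14 without sensitive sample 2 and -0.18 without resistant sample 1). It moved the median by over 1.5 times for NF-kB genes (0.31 without resistant sample 4), M1-type markers (0.24 without resistant sample 2 and 0.70 without resistant sample 3), interferon genes (0.31 without sensitive sample 2, 0.39 without sensitive sample 3 and 0.33 without resistant sample 2), neutrophil genes (1.77 without sensitive sample 1 and 1.78 without resistant sample 1), smooth muscle (0.83 without sensitive sample 5) and ribosomal proteins (0.19 without sensitive sample 1). The ribosomal median turned to -0.07 after quantile normalization and to -0.26 with the 3' to 5' ratio as a covariate.

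The 20 other lists did not pass (camera adjusted p 0.0652 to 0.913), with medians of -0.74 for M2-type markers, -0.46 for macrophage identity, 0.52 for monocyte genes, -0.22 for hypoxia and -0.34 for MHC class II. Median and mean differed in sign for lipid handling (-0.03 and 0.23), transcription factors (0.04 and -0.05), iron and heme handling (-0.23 and 0.0027), T cell chemoattractants (-0.02 and 0.34) and fibroblast markers (-0.12 and 0.15). Of the 10 lists past camera, 0 passed the exact permutation over samples (smallest adjusted p 0.286), 0 passed with an estimated correlation (0 at an unadjusted p under 0.05), and 5 lists passed without sensitive sample 2. With 126 arrangements the smallest possible exact permutation p was 0.00794, before adjustment over 30 lists. A single list could therefore not pass, so the permutation decides little here. In the activation panel no gene passed by limma. MRC1 (log2 difference -0.94, SE 0.27, adjusted p = 0.0748), CCL18 (2.50 ± 1.00) and IL6 (1.82 ± 0.89) were furthest from 0, and the 10 other genes had log2 differences of -0.76 to 0.47. The 3' to 5' ratio differed by 0.66 between these groups (exact permutation p = 0.0794 over 126 arrangements), and with it as a covariate 0 genes passed by limma (611 at an unadjusted p under 0.05). With the ratio as a covariate the camera calls of interferon genes, oxidative phosphorylation and smooth muscle ended, that of ribosomal proteins turned and 7 lists passed. Leaving out sensitive samples 4 and 5 ended the calls of interferon genes, oxidative phosphorylation, ribosomal proteins and smooth muscle and added lipid handling, lysosome, matrix genes, T cell chemoattractants and T cell markers. Other settings ended calls of ribosomal proteins with quantile normalization, with median centring, with averaged probe sets, with array weights, with the GIST marker covariate and with only the 2 groups compared and of M1-type markers, interferon genes, MHC class I and ribosomal proteins without a filter. Leaving out untreated sample 12 besides sensitive samples 4 and 5 also ended the call of neutrophil genes (camera adjusted p = 0.0526). The 60th percentile filter added immediate-early genes (camera adjusted p = 0.0226).

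**Figure D3:**
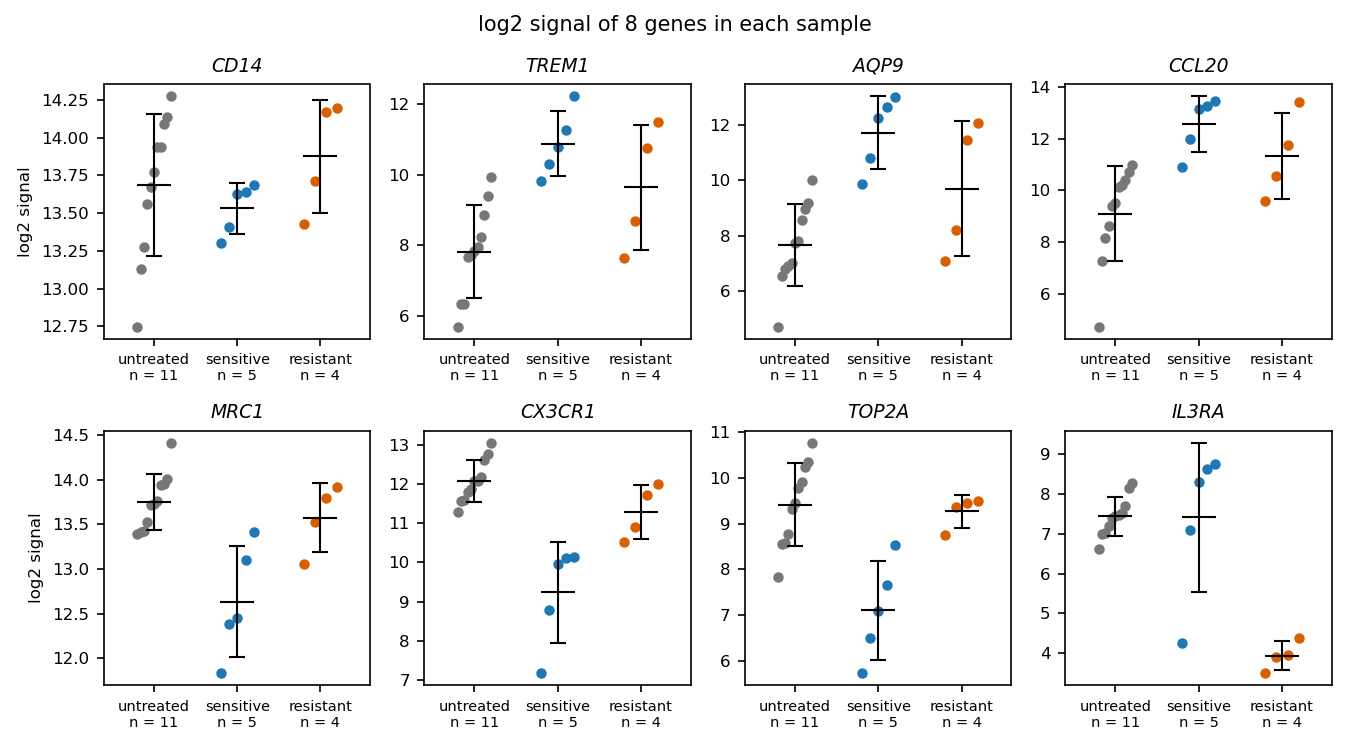
log2 signal of 8 genes in each of the 20 samples (points), with the group mean (long bar) and SD (whiskers), for untreated (n = 11), sensitive (n = 5) and resistant (n = 4) samples. MRC1, CX3CR1 and TOP2A lie lower and TREM1, AQP9 and CCL20 higher in sensitive than in untreated samples, and IL3RA lies lower in the 4 resistant samples and in 1 of the 5 sensitive samples.

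Both imatinib groups were compared with the same untreated samples. Across the 8023 genes, which are not independent replicates, the log2 differences of sensitive and of resistant samples from untreated samples had a Pearson r of 0.287. Unchanged groups simulated against the same untreated samples gave 0.289. With the untreated samples split into 5 and 6, one part for each comparison, the median r over 100 splits was 0.196 (-0.156 to 0.489). The covariance was 0.0991, against 0.0332 simulated without an effect, a difference of 0.0659.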

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

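The counts over splits of the samples and the tests that weigh the 3 patterns, some of them on planned fits, were chosen after the result was seen, except for the test of RNA degradation across all genes. With the untreated and sensitive samples split in 100 ways, the real split included, 1 of 100 gave as many genes as the 1931 found, so chance can be excluded at that share. The highest other split gave 902 and correlated with the 3' to 5' ratio at 0.51. As many as 13 lists passed in 36 of 100 (median of the other splits 12, highest 22), so for the number of lists chance cannot be excluded. Camera with the preset correlation thus called many lists in splits that mixed the groups. For resistant and untreated samples 3 of 100 splits gave at least 1 gene (highest other 4), a count that the adjustment keeps rare by construction, so this decides nothing about chance. Of these splits 16 of 100 gave at least 18 lists (median of the other splits 11, highest 23), so chance cannot be excluded. For sensitive and resistant samples 7 of 100 splits gave at least 21 genes. At least 10 lists passed in 59 of 100 (median of the other splits 10, highest 18), so chance cannot be excluded for either count. The highest other split of these samples called 1090 genes, which points to a structure of the samples; that split correlated with the 3' to 5' ratio at -0.673, and no other structure was looked for.

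For the pattern of 1489 genes lower and 442 higher in sensitive samples, scaling of the arrays is argued against as the whole cause. Of the genes called, 70.9% were lower after quantile normalization and 75.5% after median centring. The 95% interval of the 70.9%, 68.5 to 73.1, counts genes as independent trials. Genes move together, so this interval measures no spread between samples, and whether the share holds beyond these samples was not tested. Loss of tumor cells from the sort stays undecided. With the GIST marker mean as a covariate, 84.5% of the genes (1632) still passed, so that mean did not account for most calls. It was highest in untreated sample 12 (11.04). The fibroblast (10.58) and smooth muscle means (10.72) of that sample were also the highest of the untreated samples. Whether the GIST marker mean counts tumor cells alike in treated and untreated tumors was not tested. RNA degradation stays open: across genes, the slope on the 3' to 5' ratio within groups had an r of 0.354 with the log2 difference, and 14 of 100 ratios shuffled within groups gave as much (highest 0.543), while r was -0.0606 from untreated and 0.332 from sensitive samples alone. With the ratio as a covariate the median of the 1489 lower genes went from -0.67 to -0.50 and their median SE from 0.18 to 0.23, so calls ended through both, and 99.3% kept their sign. A response of the macrophages to therapy stays open as well and was not tested.

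The mean of the cell division genes differed between sensitive and untreated samples by -1.66 ± 0.41 (SE). The GIST marker mean did not account for this difference in the fit of all samples. With it as a covariate the difference was -1.95 ± 0.36, and the slope on that mean was negative (-0.43 ± 0.15). Untreated sample 12 had the highest GIST marker mean (11.04) and the lowest cell division mean of the untreated samples (7.15). How far the slope rests on that sample was not tested. Whether the marker mean counts tumor cells alike in treated and untreated tumors was not tested either, so loss of tumor cells from the sort stays undecided. RNA degradation may account for the fall, since with the 3' to 5' ratio as a covariate the difference was -0.77 ± 0.47, within 2 SE of 0, and the slope -1.36 ± 0.49. With the 3 sensitive samples inside the untreated range of the ratio alone, the difference was -0.97 ± 0.42. Their ratios of 2.21 to 2.23 still lay above the untreated mean of 1.92, so this fit does not free the difference from the ratio. Fewer dividing macrophages under therapy stay open and were not tested.

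Neutrophil and monocyte genes were higher in sensitive samples. RNA degradation is argued against as the whole cause, since the mean of both lists stayed higher by 1.81 ± 0.75 with the ratio as a covariate (slope 0.09 ± 0.78). The SE of that slope leaves room for a part of the difference to go with the ratio. Granulocytes left in the sort, which selected for CD14, cannot be told apart from a rise of these genes in the macrophages: the 5 neutrophil genes not on the monocyte list were higher by 2.55 ± 0.72, which is the pattern itself and decides nothing. Recruited monocytes in place of resident macrophages stay undecided: monocyte genes not on the neutrophil list were higher by 1.65 ± 0.51, whereas the M2-type mean of -0.35 ± 0.18 lay within 2 SE of 0. The M2-type list moved both ways, with 7 members past the gene test as lower and 3 as higher, CHI3L1 and CCL18 among the latter. Its median was -0.62, so its mean is a poor measure of resident macrophages and cannot decide this. A response to therapy stays open and was not tested.

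In groups of 4 or 5 samples, the gap between the highest or lowest sample and its neighbor was compared with the range of the group. Of 380 groups, 13 had a sample beyond Dixon's 95% limit, where chance gives about 19. In sensitive samples the gap as a share of the range, with the sample's log2 value and its neighbor's, was beyond it for ENO1 (0.718, sensitive sample 3 highest, 13.26 against 12.17), JUN (0.78, sensitive sample 2 highest, 14.24 against 14.02), LPAR6 (0.721, sensitive sample 1 highest, 11.37 against 10.80), PLIN2 (0.805, sensitive sample 3 highest, 13.84 against 12.31) and SAP30 (0.725, sensitive sample 2 highest, 10.82 against 10.04). In resistant samples it was beyond it for the 3' to 5' ratio (0.830, resistant sample 2 highest, 2.40 against 1.80), the list mean of cholesterol synthesis (0.872, resistant sample 3 highest, 9.32 against 9.10), the list mean of T cell chemoattractants (0.948, resistant sample 3 highest, 10.60 against 8.36) and the dendritic cell list mean (0.897, resistant sample 4 highest, 9.52 against 7.46). It was also beyond it there for CBX1 (0.888, resistant sample 4 highest, 10.89 against 10.25), HOXC6 (0.849, resistant sample 4 highest, 7.46 against 6.58), TAGLN (0.849, resistant sample 3 lowest, 7.52 against 8.48) and TOP2A (0.830, resistant sample 4 lowest, 8.75 against 9.36).

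The difference from untreated samples differed between sensitive and resistant samples, by the direct limma comparison, in 21 genes, and by camera in 10 lists. Of these lists 0 passed with an estimated correlation and 0 by exact permutation, which no single list could pass with so few arrangements. Of 1426 probe sets bright enough to be tested but without a single listed gene, 265 passed in sensitive versus untreated samples (89 higher, 176 lower). In sensitive versus resistant samples 8 of them passed, all lower.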

How the results depend on the processing

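Fits without the 2 sensitive samples of highest 3' to 5' ratio, and without those 2 and untreated sample 12, were chosen after seeing the data, and the others were planned. The count of 1931 genes in sensitive versus untreated samples was 1532 to 2048 under 10 settings (another offset, 2 other scalings, 2 filters, averaged probe sets, the pair as 2 samples, the GIST marker covariate, plain eBayes and only the 2 groups), and 2852 of all probe sets tested singly. It was 1253 with array weights, 93 with the ratio as a covariate, 550 without the 2 samples, 676 without the 3 and 1165 (without sensitive sample 5) to 2488 (without sensitive sample 1) leaving out 1 sample. Of the genes named, 100 lost their call with the ratio, 68 without the 2 samples and 39 with array weights. The count of 13 lists was 3 by exact permutation, 0 by camera with an estimated correlation and 12 to 16 leaving out 1 sample. It stayed within 1.5 times elsewhere, though with the ratio 4 ended and 3 were gained.

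In resistant versus untreated samples the 1 gene by limma became 0 with log2 of the value plus 50 (821 at an unadjusted p under 0.05), with quantile normalization (764), with the 60th percentile filter (641), which leaves out IL3RA, and with the GIST marker covariate (458). Leaving out 1 sample gave 0 (without untreated sample 1, for example) to 2 (without sensitive sample 2) genes. Its 18 lists became 0 by permutation, 0 by camera with an estimated correlation and 15 to 19 leaving out 1 sample, while with quantile normalization 4 ended and 4 were gained and with the GIST marker covariate 3 ended and 4 were gained. In sensitive versus resistant samples the 21 genes by limma became 13 with log2 of the value plus 50, 13 without a filter, 39 with the 60th percentile filter and 39 with averaged probe sets. They became 54 among all probe sets, 67 with median centring, 75 with the pair as 2 samples and 126 with the GIST marker covariate. They became 1 with array weights, 1 without the 2 samples, 3 without the 3, 0 with the ratio (611 at an unadjusted p under 0.05), 0 with only the 2 groups (1262) and 0 (without sensitive sample 4, for example) to 802 (without sensitive sample 1) leaving out 1 sample. Its 10 lists became 0 by permutation, which no single list could pass with so few arrangements, and 0 by camera with an estimated correlation. They became 6 without a filter and 5 (without sensitive sample 2) to 13 (without sensitive sample 4) leaving out 1 sample, and with the ratio 3 ended and 0 were gained.

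The ribosomal median changed sign. In sensitive versus untreated samples it was -0.17 with quantile normalization, -0.29 with the ratio, -0.11 without the 2 samples, -0.10 without the 3 and -0.086 (without sensitive sample 5) to 0.19 (without sensitive sample 1) leaving out 1. In sensitive versus resistant samples it was -0.074, -0.26, -0.11 and -0.11 under the same settings in that order and -0.063 (without sensitive sample 5) to 0.19 (without sensitive sample 1) leaving out 1. In resistant versus untreated samples the ribosomal median of -0.036 ranked higher in camera and ranked lower at -0.12 with quantile normalization, and was -0.078 (without resistant sample 2) to 0.012 (without resistant sample 1) leaving out 1. The cell division median there, -0.038 and ranked higher, ranked lower at -0.44 with the GIST marker covariate, and was -0.15 (without untreated sample 12) to 0.11 (without resistant sample 4) leaving out 1. With averaged probe sets DUSP1 was -0.17 and CD4 0.016 in sensitive versus untreated samples. Median centring moved the median of all genes in resistant versus untreated samples from -0.051 to 0.068 and in sensitive versus resistant samples from -0.088 to -0.20. For all of these shifts the cause was not tested. For genes whose signal lay under the filter in 1 group, the background limits how well the size of the difference is known.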

Other observations

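No tests were made in this part, and its samples were singled out after their values were seen. Sensitive sample 1 differed from the other sensitive samples in IL3RA and in its neutrophil genes. Its log2 signal of IL3RA was 4.27, against 7.10 to 8.76 in the other 4 sensitive and 3.49 to 4.37 in resistant samples. Its neutrophil list mean was 7.53, against 9.89 to 11.76 in the other sensitive samples and 6.59 to 9.52 in untreated samples. PTGDS stood at 12.11 in it, 9.24 to 11.20 in the other sensitive and 5.52 to 8.11 in resistant samples.

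The endothelial list mean was 7.38 to 10.36 in untreated, 8.19 to 10.61 in sensitive and 6.45 to 8.37 in resistant samples. The first principal component held 28.8% and the second 20.4% of the variance. Sensitive samples 4 and 5 and untreated sample 12 had the highest scores on the first, at 61.2, 74.7 and 52.5. Osteopontin (SPP1) had log2 signals of 7.04 to 14.59 in untreated and 13.63 to 15.24 in resistant samples.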
